A study of Antirrhinum majus with 4 samples.

How the data were processed

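Small RNA was enriched from total RNA of corollas, made into libraries with high-definition adapters, which carry random bases at the ligation ends, and sequenced on an Illumina HiSeq, per the labels' protocols. Each library pooled 5 to 6 corollas of 2 to 3 plants, from buds of 10 to 30 mm, and the plants were grown together, per the labels. Nothing says that the 2 libraries of a line shared no plant, so that p-values measure the spread between these libraries. The authors deposited, per sample, a list of distinct sequences with the count of reads of each, not normalized. The sequences were 17 to 32 nt long. The adapter trimmer, the length filter and any aligner or genome build are not given in the sources used here. No reference genome was used here, so that no small RNA was given a genome position.

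Groups, tests, lists of families, the rule for named items and most alternatives were fixed before the data were examined. The line was the only term of each model. Counts of distinct sequences of 18 to 28 nt that reached 1 CPM in at least 2 libraries were tested with edgeR 4.0.16 (quasi-likelihood, TMM factors, library size the total of all reads, adjusted p under 0.05 after Benjamini-Hochberg) in R 4.3.3. The same filter was used for loci, for which none had been set in advance. DESeq2 1.42.0 served as an alternative. The standard error of a log2 fold change was taken as its size divided by the square root of edgeR's F statistic. Fold changes are JI660 over JI661, so that negative values are lower in JI660. In counts simulated from the means of the 74313 tested sequences, 94% of sequences changed 16-fold were found, and 5 of 136 calls were false. The simulation gave all sequences 1 common dispersion, so that these shares may not carry over to the data. The intervals and floors given cover counting error only, since reads amplified by PCR are not independent molecules.

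Tags of the glucosyltransferase were found by translation in 6 frames. A tag matched if a translation of 6 to 8 amino acids without a stop lay in the protein. The protein sequences, the miRNA families and the rRNA and tRNA fragments were written from background knowledge, and no reference was used to check them, so that a difference of 1 amino acid can lie in the sequence used. The reversed protein and 20 shuffled versions measured chance matches; the search found all of 1000 planted tags and matched 2 of 100000 random ones. The sum of the matching tags was tested as a further line of the table of loci. The covered codons were the 20-codon stretches that held more JI661 reads than a whole shuffled protein did on average, a choice made after the data were seen, as were the grouping of sequences by an overlap of 15 nt and the search with 1 or 2 substitutions.

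Loci were contigs of tags of 20 to 24 nt with at least 4 reads over the 4 libraries, joined without a reference (k = 19, at least 50 nt). The 2686 contigs had a longest length of 172 nt and took up 442836 and 425549 reads of JI660 and 417017 and 314878 of JI661, a small part of each library. They are numbered in the order of assembly. Tags of 20 to 22 nt belonged to a miRNA family if their first 18 nt matched a listed sequence with at most 1 mismatch, and families with at least 10 reads in 2 libraries were tested with the library sizes of the sequence table. Shares of length, strand and fragments were compared by exact two-sided permutation tests. The named sequences and loci are the 10 with the smallest p in each direction among those past the threshold whose lines do not overlap in CPM, with overlapping ones left out of the text, and the 10 most abundant exact matches of the glucosyltransferase; all tested families were open to naming.

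Replicates of a line differed by more than sampling noise (chi-square per degree of freedom 4.68 in JI660 and 5.49 in JI661), and each library was kept as a separate sample. Alternatives were each library left out, the replicate number as a block, DESeq2, other scalings, other filters on low counts, other length ranges, other contigs and other matching rules. A count of families with the 5' end moved by 1 base, a test without sequences holding adapter, and 2 further sums for the glucosyltransferase were added after the data were seen. That count of families also matched further miRNA sequences added to the list. Tables were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots with Matplotlib 3.10.9.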

Results

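Small RNAs were sequenced from the corollas of Antirrhinum majus (snapdragon), in line JI660, which carries the mutant allele sulf, and in line JI661, a revertant that carries SULF again. SULF limits the yellow aurone pigments to parts of the petal and is known as an inverted duplication derived from the gene for chalcone 4'-O-glucosyltransferase, an enzyme of aurone synthesis. There were 2 libraries per line. The comparison asked which small RNAs of the corolla differ between the mutant and the revertant, first of all those that match the glucosyltransferase. The JI660 libraries held 16969849 and 16909976 reads and the JI661 libraries 17158418 and 13302897 reads. Together they held 19990269 distinct sequences, and 79.7% to 81.2% of the distinct sequences of a library were read once. Levels are given as CPM, counts scaled to the total reads of the library, as mean ± SD over 2 libraries.

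Small RNAs matching the glucosyltransferase were abundant in JI661 and scarce in JI660. Tags whose translation lay in the protein reached 660 ± 96.1 CPM (SD, n = 2) in JI661 and 33.7 ± 7.85 CPM (SD, n = 2) in JI660. The reads numbered 12489 and 7874 in the JI661 libraries and 666 and 476 in the JI660 libraries. The log2 fold change of JI660 over JI661 was -4.43 (SE 0.49), a 21.5-fold difference that passed edgeR's quasi-likelihood test (adjusted p = 8.2e-05), and both JI660 libraries lay below both JI661 libraries. With the mean of shuffled proteins subtracted, a choice made after the data were seen, the difference was 45.96-fold (log2 fold change -5.52, SE 0.54). This SE takes the subtracted mean as exact. The SD among shuffled proteins was 317 and 239 reads in JI660, where 332 and 188 reads were left. The corrected fold thus has no firm upper limit. Chalcone synthase, an earlier enzyme of the same pathway, was matched at 11.3 ± 1.39 CPM (SD, n = 2) in JI660 and 11.5 ± 2.82 CPM (SD, n = 2) in JI661. Its log2 fold change was -0.16 (SE 0.17, edgeR adjusted p = 0.722), but these matches did not exceed the chance background of the search and give no level of small RNAs of that gene. The background of the search, measured with 20 shuffled versions of the glucosyltransferase protein, averaged 19.7 and 17.04 CPM in JI660 and 21.9 and 17.1 CPM in JI661. In JI661 the real protein was matched by 33.3 and 34.6 times as many reads as the mean shuffled protein. In JI660 it was matched by 2.00 and 1.65 times as many, within the range of single shuffled proteins (107 to 1292 reads in replicate 1 and 80 to 1031 in replicate 2).

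Most of the matching reads fell in a central stretch of the protein sequence used, and they came from both strands. Stretches where that sequence is wrong would give no match, so the extent of the small RNAs along the gene is not known. Codons 141 to 300 of the 457 codons were chosen from these JI661 reads. They held 97.6% and 97.8% of the matching reads in JI661, and 81.5% and 77.9% in JI660. Over these codons the level was 710.4 and 579 CPM in JI661 and 31.998 and 21.94 CPM in JI660. Antisense frames held 71.1% ± 0.0960 (SD, n = 2) of the matching reads in JI661 and 66.4% ± 4.44 (SD, n = 2) in JI660. This share did not separate the lines beyond what 2 against 2 libraries can show (exact two-sided permutation p = 0.333, the smallest such a design allows). Over distinct sequences the direction turned, with 58.1% ± 0.558 (SD, n = 2) antisense in JI661 and 58.8% ± 1.58 (SD, n = 2) in JI660. The JI660 shares over the whole protein include much chance background. A shuffled protein averaged 621.8 reads over the 2 JI660 libraries and 602.5 over the JI661 ones. Within codons 141 to 300 antisense frames held 72.2% and 66.3% of the reads in JI660 and 71.4% and 71.5% in JI661. In JI661 52.9% ± 0.424 (SD, n = 2) of the matching reads were 21 nt long and 30.6% ± 1.61 (SD, n = 2) were 22 nt long, while 24 nt reads made up 3.00% ± 0.357 (SD, n = 2). Sense and antisense reads were unevenly placed. In JI661 codons 161 to 180 held 188.2 and 147.6 CPM of antisense reads against 21.7 and 16.9 CPM of sense reads, and codons 201 to 220 held 92.0 and 79.8 CPM of sense reads against 38.7 and 34.7 CPM of antisense reads.

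**Figure D1:**
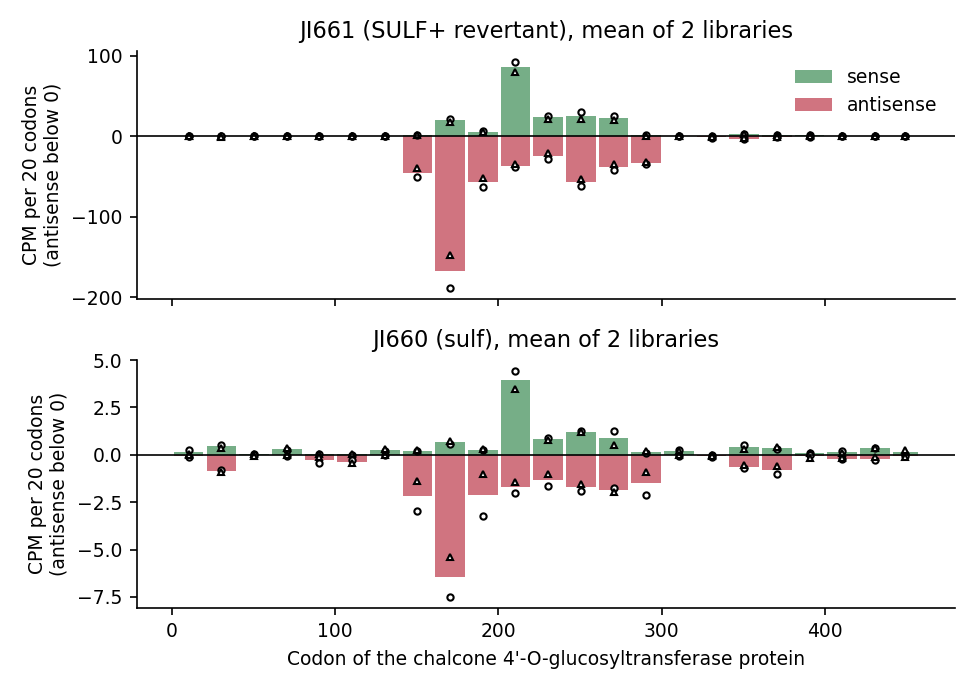
CPM of tags with an exact match to the chalcone 4'-O-glucosyltransferase protein per stretch of 20 codons, sense frames above 0 and antisense frames below. Bars are means of 2 libraries, circles replicate 1 and triangles replicate 2. The y axes differ between the panels: antisense reads of codons 161 to 180 reached 188.2 and 147.6 CPM in JI661 (upper panel) and 7.48 and 5.38 CPM in JI660 (lower panel).

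The most abundant tag with an exact match was the antisense 22 nt sequence ACAAACTCATTGGCAAATCAGA, whose reverse complement encodes the peptide SDLPMSL from codon 180. It reached 61.1 ± 5.82 CPM (SD, n = 2) in JI661 and 2.24 ± 0.579 CPM (SD, n = 2) in JI660. Its 21 nt form ACAAACTCATTGGCAAATCAG stood at 24.98 ± 3.00 against 0.708 ± 0.583 CPM (SD, n = 2), and the antisense tag TTGGCAAATCAGAAGAGTGAA at 21.9 ± 7.32 against 0.738 ± 0.207 CPM (SD, n = 2). On the sense strand AAACATGCGCAAATCGAGCGGG, which encodes NMRKSSG from codon 203, stood at 11.98 ± 0.705 against 0.472 ± 0.00118 CPM (SD, n = 2). The 10 most abundant exact matches were higher in both JI661 libraries than in both JI660 libraries. They were ranked by reads pooled over both lines, most of which came from JI661, so this adds no support.

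Over all single sequences, those lower in JI660 outnumbered those higher, and most of the lower ones belonged with the glucosyltransferase. Of 74313 sequences tested, 544 were lower and 137 higher in JI660 (edgeR, adjusted p under 0.05). Of the lower ones, 528 were free of sequencing adapter, and of these 95 matched the protein exactly and 253 with at most 1 amino acid different. The shuffled proteins gave no exact match among them, and at most 7 with 1 difference. Together with sequences that overlapped an exact match by 15 nt or more, directly or through others, 341 of the 528 (64.6%) belonged to the glucosyltransferase group. These 341 summed to 3568 ± 625 CPM (SD, n = 2) in JI661 and 94.9 ± 20.2 CPM (SD, n = 2) in JI660. Of the 341, 184 were 21 nt and 82 were 22 nt long. By level, 67.2% of their JI661 CPM was 21 nt, 17.05% was 22 nt and 4.08% was 24 nt long. Among all tested sequences 21 nt made up 11.7%, among the lower ones 44.5%.

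The most abundant sequence of this group, AGAGTGAATCAATGGGCACCC, reached 1262 ± 270.3 CPM (SD, n = 2) in JI661 and 30.1 ± 5.14 CPM (SD, n = 2) in JI660, a log2 fold change of -5.42 (SE 0.31, edgeR adjusted p = 0.000446). It held 35.4% of the group's JI661 level. Its reverse complement encodes GCPLIHS, which differs by 1 amino acid from the protein sequence used, so that it was not part of the exact matches above. The named sequences that overlap it, such as CAGAAGAGTGAATCAATGGGCACC (log2 fold change -5.64, SE 0.30) and AGTGAATCAATGGGCACCCGG (-5.58, SE 0.30), had similar values. Also within the glucosyltransferase group, a further set of 83 overlapping sequences held 7 exact matches and AACAGTTTGGTGTAGCCTTGG. This set summed to 728.2 and 626.3 CPM in JI661 and 21.3 and 15.9 CPM in JI660. AACAGTTTGGTGTAGCCTTGG itself stood at 106 ± 22.99 against 2.80 ± 0.202 CPM (SD, n = 2), a log2 fold change of -5.26 (SE 0.29).

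**Figure D2:**
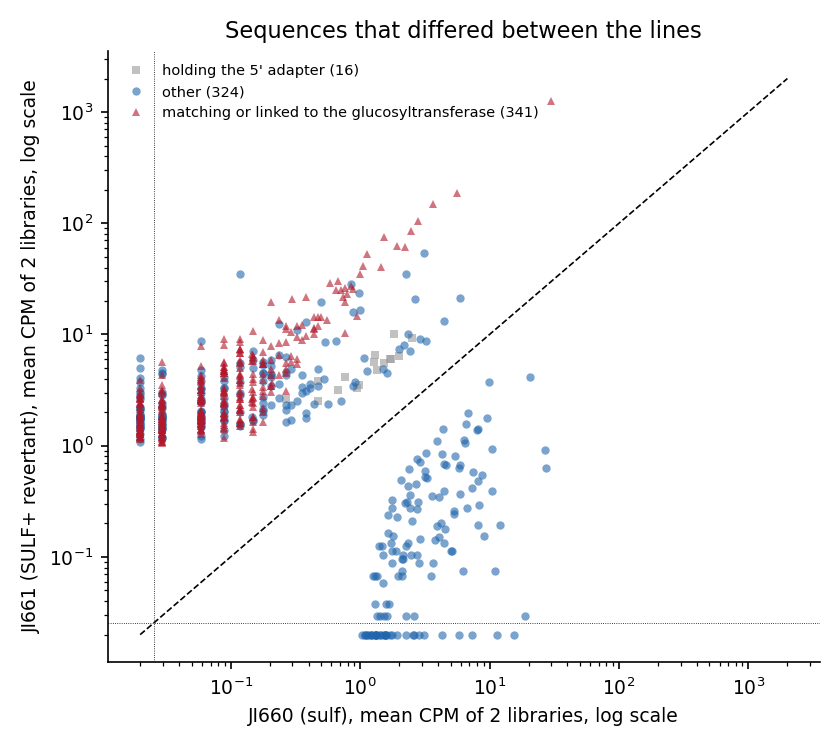
Mean CPM of the 681 sequences that differed between the lines, JI660 on the x axis and JI661 on the y axis, both on log scales, by class; points beyond the dotted lines had 0 reads in both libraries of a line, and the dashed line marks equal levels. The 341 sequences of the glucosyltransferase group lie above the dashed line, as do the 16 that held adapter, and the 137 sequences higher in JI660 lie below it.

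The 137 sequences higher in JI660 were mostly 24 nt long (102 sequences, 74.5%, against 58.5% of all tested sequences), and none had an exact match to the glucosyltransferase. They summed to 585 ± 61.6 CPM (SD, n = 2) in JI660 and 46.3 ± 4.02 CPM (SD, n = 2) in JI661. CCCTACCCAAGCCAAAGTGGCACC had 636 reads in JI660 and 1 in JI661, a ratio of 572 with a 95% counting interval of 102 to 22600. Its 21 nt form TACCCAAGCCAAAGTGGCACC stood at 15.3 ± 2.01 CPM (SD, n = 2) in JI660 and had 0 reads in both JI661 libraries, so it was at least 156-fold higher against a floor of 3 reads over the line. CCATATGAGAATTCTGACAGTCAT, also at 0 in JI661, was at least 115-fold higher. ACGAGGCAAGACAAGGATTGAGAC stood at 26.9 ± 0.267 against 0.909 ± 0.116 CPM (SD, n = 2; log2 fold change 4.84, SE 0.29, edgeR adjusted p = 0.000446). CTAACCCTTGTGTCGAATACCGAG had a log2 fold change of 5.85 (SE 0.41) and the 21 nt AGGAGGCGGAGAAGCGCGTAA one of 5.70 (SE 0.42). Of the 137, 33 had no read in either JI661 library.

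All 681 sequences separated the lines without overlap, which passing the test with 2 libraries per line nearly requires, so this adds no support. Of all tested sequences 43.4% did so, and chance gives 33.3%. In data simulated with 1 dispersion common to all sequences the test found 8% of sequences changed 2-fold, 68% of those changed 4-fold and 92% of those changed 8-fold. Small differences would thus mostly be missed at this number of libraries, though the shares found in the real data may differ. The counts fell or rose widely when a single library was left out. A line then held 1 library, assumed to vary like the other line. Why the counts moved was not tested. The 16 lower sequences that held at least 12 nt of the 5' sequencing adapter stood at 19.8 ± 4.06 CPM (SD, n = 2) in JI660 and 83.2 ± 23.99 CPM (SD, n = 2) in JI661. With all sequences holding adapter left out of the test, a choice made after the data were seen, 173 were higher and 573 lower.

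At the level of loci, small RNAs differed in both directions. Loci were contigs of overlapping tags built without regard to the line, with no genome position. Of 2673 tested, 39 were higher and 34 lower in JI660 (edgeR, adjusted p under 0.05), and in all 39 of the higher and 32 of the lower ones at least 50% of the reads were 24 nt long, as in 2456 (91.9%) of all tested loci. Only contig_1780, of 54 nt, shared 15 nt or more with the glucosyltransferase group. It stood at 57.1 ± 0.984 CPM (SD, n = 2) in JI661 and 1.27 ± 0.289 CPM (SD, n = 2) in JI660 (log2 fold change -5.61, SE 0.20, edgeR adjusted p = 2.17e-10), and 23.9% of its reads were 21 nt long. This was a small part of the 3568 CPM that the glucosyltransferase group summed to in JI661. The counts of differing loci thus hardly represent that group. A few 24 nt loci were present almost entirely in 1 line. Contig_536, with the most abundant tag ATGATAAACCCATGACACAAGAGT, had 305 and 215 reads in JI661 and 0 in JI660, at least 192-fold lower against a floor of 3 reads over the line. Contig_1027, with the tag ATTTGAGTTACTTTGGCATTCGGG, had 865 reads in JI661 and 3 in JI660, a ratio of 321 with a 95% counting interval of 109 to 1560. In the other direction contig_2491, with the tag ATTGTGTTGTCACTCGAGATTTGC, had 127 and 129 reads in JI660 and 1 in each JI661 library, a ratio of 115 with an interval of 31.5 to 955. Contig_2499, with the tag TGAGACTCTACCTTTGAAACGGGA, stood at 20.04 ± 3.58 against 0.775 ± 0.140 CPM (SD, n = 2; log2 fold change 4.52, SE 0.22), and contig_609, with AAAGTCGTTCTTCAGCTCACTCGA, at 51.4 ± 2.00 against 8.78 ± 0.875 CPM (SD, n = 2; log2 fold change 2.43, SE 0.15).

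The median log2 fold change of the differing loci was 0.94 for those higher and -1.04 for those lower in JI660. The split between directions depended on the scaling. Scaled by total reads, which moved the median of all loci from -0.01 to 0.12, 99 loci were higher and 32 lower (75.6% higher, against 53.4%), and scaled by the miRNA families, with a median of 0.13, 30 were higher and 13 lower (69.8% higher). The counts also changed with single libraries: 80 higher and 88 lower without JI660 replicate 2, 23 and 17 without JI661 replicate 1, and 16 and 19 without JI661 replicate 2.

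Conserved miRNAs were read in both lines, and no family passed the test between them. Of 32 families and tasiRNAs looked for, 23 had enough reads, and 0 differed by edgeR (2 at an unadjusted p under 0.05) or by DESeq2 (1 at an unadjusted p under 0.05). Counted from the listed 5' ends, the most abundant was miR159, a regulator of GAMYB transcription factors, at 3576 ± 1415 CPM (SD, n = 2) in JI660 and 5071 ± 752 CPM (SD, n = 2) in JI661. miR168, which targets ARGONAUTE1, stood at 2599 ± 267 and 2137 ± 275 CPM (SD, n = 2), and miR319, which targets TCP genes of petal and leaf growth, at 1252 ± 112 and 1721 ± 365 CPM (SD, n = 2). With forms that begin 1 base away also counted, miR319 stood at 4559 and 7014 CPM, above miR159 at 3589 and 5091 CPM. Among the 10 families of petal and meristem development 0 passed, also when adjusted over the list alone. miR396, a regulator of growth-regulating factors, had a log2 fold change of 0.48 (SE 0.38), miR165 with miR166, which target HD-ZIP III genes, of -0.03 (SE 0.27), and miR172, which targets AP2 genes, of -0.33 (SE 0.22). Of the 5 auxin families, which include miR160, miR167, miR390, miR393 and tasiR-ARF, 0 passed, and their log2 fold changes lay between -0.24 and 0.29.

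**Figure D3:**
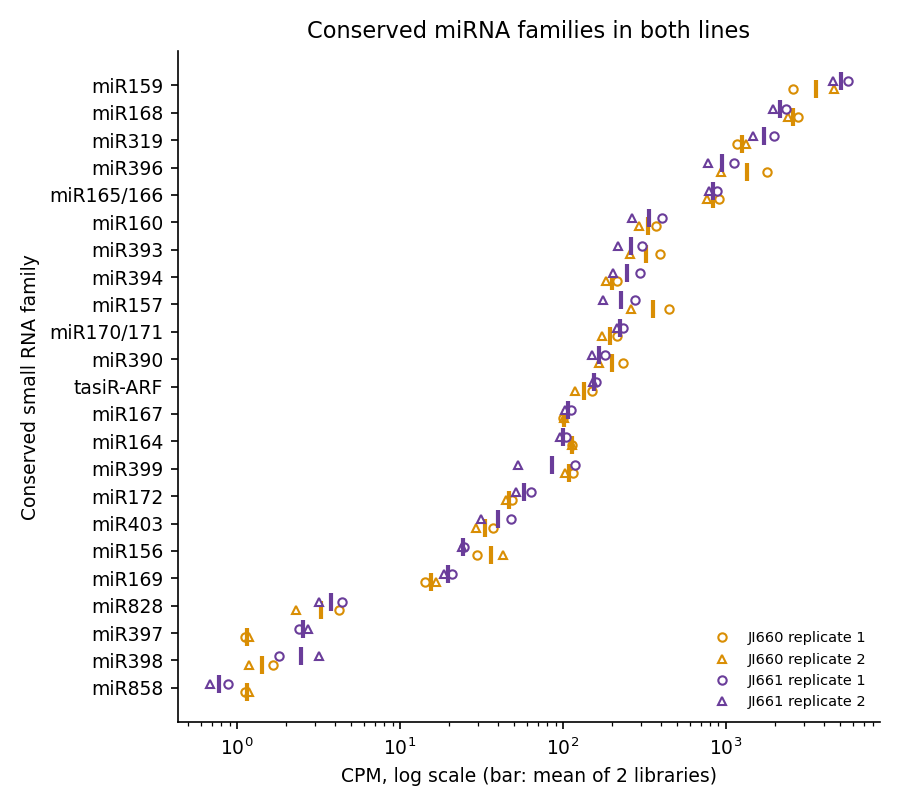
CPM of the 23 tested families of conserved miRNAs and tasiRNAs on a log axis; circles are replicate 1, triangles replicate 2 and bars the mean of 2 libraries of a line. Only tags with the listed 5' ends are plotted, so that miR858 (1.15 CPM in JI660 and 0.775 CPM in JI661) and miR319 lack their most abundant forms, which begin 1 base away. miR159 (3576 and 5071 CPM) is the highest family plotted, and none passed the test.

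Of the list of leaf polarity and nutrient or copper stress, 4 of 7 families were measured and 1, miR397, passed when adjusted over the list alone (edgeR adjusted p = 0.00923), but not over all families (adjusted p = 0.0531). miR397, which targets laccases, was scarce, at 1.15 ± 0.0446 CPM (SD, n = 2) in JI660 and 2.55 ± 0.224 CPM (SD, n = 2) in JI661 (log2 fold change -1.17, SE 0.26). miR398, which targets copper superoxide dismutase genes, stood at 1.42 ± 0.330 and 2.48 ± 0.955 CPM (SD, n = 2; -0.82, SE 0.35). Without JI661 replicate 1 both miR397 and miR398 passed (edgeR adjusted p = 0.0329 for each), and miR397 passed when scaled by total reads (edgeR adjusted p = 0.0328). Of the regulators of flavonoid MYB genes, miR828 stood at 3.27 ± 1.37 and 3.76 ± 0.858 CPM (SD, n = 2), and neither it nor miR858 passed the test. The silencing regulators miR168 and miR403 did not pass either. The listed forms of miR2118 and miR2275 had 0 reads in each library, and miR845 had 1 read in 1 library, or 5 and 8 in JI660 and 5 and 1 in JI661 with shifted ends. The listed forms of miR482 and miR535 also had 0 reads, although miR482 was abundant in the count with shifted ends and added sequences. These zeros thus set no upper level, and 0 of the 4 triggers of anther and defence phasiRNAs could be tested in the main count.

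In both lines 24 nt small RNAs were the most frequent class. The 24 nt class held 48.4% ± 0.229 (SD, n = 2) of the reads of 18 to 28 nt in JI660 and 45.1% ± 2.56 (SD, n = 2) in JI661. The 21 nt class held 14.2% ± 0.700 and 15.7% ± 2.21 (SD, n = 2), and the 22 nt class 9.96% ± 0.395 and 10.4% ± 0.481 (SD, n = 2). The difference in the 24 nt share had an exact two-sided permutation p of 0.333, the smallest this design allows, and those in the 21 and 22 nt shares one of 0.667. Over distinct sequences the 24 nt shares of the lines overlapped, at 49.7% and 50.2% in JI660 and 46.2% and 50.5% in JI661. Of the 24 nt reads 48.4% ± 0.933 (SD, n = 2) in JI660 and 47.5% ± 0.431 (SD, n = 2) in JI661 began with A, the base typical of heterochromatic siRNAs. Of the 21 nt reads 33.7% ± 0.196 and 34.6% ± 1.25 (SD, n = 2) began with T, the base typical of miRNAs.

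**Figure D4:**
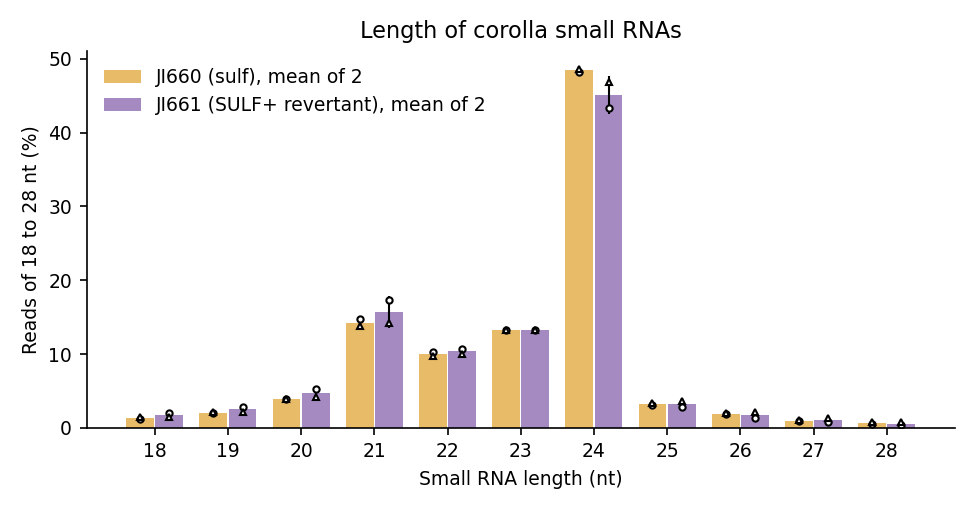
Share of the reads of 18 to 28 nt (y axis, %) by length (x axis, nt); bars are the mean of 2 libraries, error bars the SD, circles replicate 1 and triangles replicate 2. In both lines 24 nt was the most frequent length, at 48.4% in JI660 and 45.1% in JI661.

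Fragments of the listed molecules (5S and 5.8S rRNA and a few tRNAs; 18S and 25S rRNA were not searched) held 0.185% ± 0.0140 (SD, n = 2) of the reads of 18 to 28 nt in JI660 and 0.174% ± 0.0261 (SD, n = 2) in JI661. Over all lengths they held 0.313% ± 0.0295 (SD, n = 2) in JI660 and 0.231% ± 0.000871 (SD, n = 2) in JI661, and the listed tRNA fragments alone 0.179% ± 0.0216 and 0.0968% ± 0.0147 (SD, n = 2), without overlap of the lines (exact two-sided permutation p = 0.333 for each). The plastid tRNA-His fragment, a sign of green tissue, held 0.00164% ± 0.000353 and 0.00163% ± 0.000221 (SD, n = 2). The library JI661 replicate 1 held more short reads than the others: 11.4% of its reads were 17 to 20 nt long, against 7.60%, 8.17% and 8.23% in JI660 replicates 1 and 2 and JI661 replicate 2. Tested sequences holding adapter summed to 14550 and 18640 CPM in JI660 and to 22990 and 40650 CPM in JI661.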

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

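Lower levels of glucosyltransferase-matching small RNAs in JI660 passed the threshold under each alternative run, with log2 fold changes from -5.52 to -4.23; the former subtracted the shuffled proteins and, like the sum over covered codons only (-4.72), was chosen after the data were seen. Of 260 alternative values for the 20 named sequences, 260 kept direction and call, and of 200 for the 20 named loci 199 did; contig_1742 lost its call without JI661 replicate 1.

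The named sequences and loci had the smallest p in each direction, so their stability does not extend to the other calls. Counts of all differing items moved more, and the cause was not tested unless stated. With a replicate block 1253 sequences were lower, and 70 loci were higher and 73 lower; the replicate numbers are not known to mark pairs, and the differences between replicates correlated at 0.112 between the lines across sequences. With at least 10 reads over the libraries, which tests more sequences, 244 were higher and 973 lower, and with 5 CPM, which tests fewer, 23 and 92. DESeq2 called 21 loci higher and 19 lower, total reads 99 higher, miRNA scaling 13 lower, contigs with k = 17, which gave more loci, 84 and 69, and contigs of tags with at least 10 reads, which gave fewer, 11 and 6. Leaving out single libraries, where the lone library is assumed to vary like the other line, gave 82 to 566 sequences higher and 471 to 2597 lower, 16 to 80 loci higher and 17 to 88 lower, and 0 to 2 miRNA families. Scaled by total reads 1 family passed. The 24 nt share of JI660 exceeded that of JI661 by 1.53 percentage points over distinct sequences, against 3.35 over reads, and the lines then overlapped. The share of the listed rRNA and tRNA differed by 0.0819 points over all lengths. The antisense share of JI660 was 0.705 points above that of JI661 over distinct sequences but lay below it over reads (-4.71). Chance matches weigh more in the JI660 share. The rarer families rest on few reads, such as miR397 with 19 and 20 reads in JI660.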

Other observations

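Some abundant small RNAs lay outside the lists as first matched. The most abundant sequence of all, TTTCCAATTCCACCCATTCCAA, has the form of the miR482 family, which targets disease resistance genes, and stood at 9519 ± 694 CPM (SD, n = 2) in JI660 and 11303 ± 1346 CPM (SD, n = 2) in JI661. The main form of miR858, a regulator of flavonoid MYB genes, was TCCGTTGTCTGTTCGACCTTG, at 2173 ± 68.0 and 2650 ± 407 CPM (SD, n = 2), and began 1 base away from the listed sequence. With forms moved by 1 base and the added sequences counted, miR319 reached 4559 ± 264 CPM (SD, n = 2) in JI660 and 7014 ± 1285 CPM (SD, n = 2) in JI661 (log2 fold change -0.65, SE 0.27, edgeR adjusted p = 0.284), and miR858 had a log2 fold change of -0.32 (SE 0.26). No family passed edgeR's test in this count either, and 3 (miR397, miR408 and miR319) had an unadjusted p under 0.05. The unnamed 21 nt sequence ATCTGAGTGACTTGCACCTGA came next in abundance, at 5565 ± 466 and 7246 ± 1863 CPM (SD, n = 2).

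Of the lower sequences without adapter, 187 were not placed in the glucosyltransferase group by the matching and overlap rules used. They summed to 852 ± 68.2 CPM (SD, n = 2) in JI661 and 65.5 ± 8.85 CPM (SD, n = 2) in JI660, and 88 of them were 21 or 22 nt long. Of the 187, 51 resembled the protein within codons 141 to 300 with up to 2 substitutions, against at most 27 for a shuffled protein. The most abundant was the 21 nt ACAACTGCCGAAACACACCGA, at 54.2 ± 0.798 CPM (SD, n = 2) in JI661 and 3.10 ± 2.12 CPM (SD, n = 2) in JI660, in a group of 28 overlapping sequences. It was chosen after its value was seen, as was AATATCTTTGTGAACTGGCATCGA, of 24 nt, at 34.9 ± 1.42 against 0.118 ± 0.167 CPM (SD, n = 2).

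The tests of spill-over, chance matches, a shared precursor and chance resemblance were chosen after the results were seen; that of base variants was set before its result. JI660 still held small RNAs of the covered codons of the glucosyltransferase, 914 reads against 19892 in JI661, or 4.59%. The ratio was 3.76% over these codons and 2.63% over the whole protein with the mean of the shuffled proteins subtracted, its spread ignored. Spill-over of reads from the JI661 libraries would leave at least this ratio at each locus of JI661, but 3 loci fell below 4.59% and 2 below each corrected ratio by more than counting error, and contig_1027 had 3 reads where 32.5 would follow at 3.76% and 22.8 at 2.63% (Poisson p times 2673 loci = 1.27e-07 and 0.000775). Chance matches of the search do not account for them either, since JI660 held 395 distinct matching sequences there and a shuffled protein at most 103. The JI660 counts ranked like the JI661 counts over 293 sequences (Spearman rho 0.572), as a precursor of the same kind at a low level would give, which stays open as a hypothesis. Whether it may come from the sulf allele, from cells that regained SULF or from another gene copy was not tested.

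The sequences that differed outside the glucosyltransferase group may mark segments where the genomes or their siRNA loci differ between JI660 and JI661. Single base variants between the lines would give a counterpart of the same length with 1 mismatch that goes the other way. Of 324 sequences outside the group 0.0% had one (95% Clopper-Pearson upper limit 1.13%), against 0.586% of 3240 draws of sequences not called, matched in length and abundance. Many of the 324 overlap one another, as in groups of 11 and 10 sequences higher in JI660, so that this limit is too narrow. Those that may belong with the glucosyltransferase need not have a counterpart in any case. Insertions, deletions or larger diverged segments, and silencing without any sequence change, stay open as untested hypotheses.

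Within the sequences higher in JI660, 6 sequences of 21 nt, among them AGGAGGCGGAGAAGCGCGTAA, summed to 17.4 and 24.1 CPM in JI660 and 0.641 and 0.451 CPM in JI661 and resembled 1 stretch of the glucosyltransferase with up to 2 substitutions. At most 6 sequences fell within 10 codons, and a shuffled protein also reached 6, so the resemblance may be chance.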
